A study of Bos taurus with 6 samples.

How the data were processed

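The data were 6 scanned 2-colour arrays of bovine oviduct epithelial cells, cultured for 13 days with SOF medium (synthetic oviduct fluid, a medium for embryos) in the later part, with embryos added on day 5 or without them. Per the labels' protocols, 500 ng of each total RNA was amplified and labelled with Cy3 or Cy5. The direction of each ratio was taken from the dyes in the labels, and the labels call the 3 pairs biological replicates. Whether a pair of cultures came from the same oviducts is not given in the sources used here.

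The scanner files hold the intensity of each spot and of its local background per channel, written by Feature Extraction 9.1.3.1 per the file headers, with no normalization in the mean and background columns. The processed signals in the same deposited files are background-subtracted and dye-normalized intensities, per the file headers. The authors' deposited value table holds log2 values. Each of its columns equalled the mean log2 median-pixel signal of both channels of 1 scanner file within 0.001 for 99.98% of filled cells, so it holds no embryo/control ratio and no centring. The column medians were 6.84 and 7.64 for replicate 1, 6.53 and 6.98 for replicate 2, and 6.54 and 6.98 for replicate 3. The columns named for replicates 2 and 3 matched each other's scanner files. The dye orientation was the same in both, so neither the direction nor n changes, but which of the 2 numbers belongs to which pair is open. The scanner files were taken as GEO assigns them.

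The array has 48 print blocks of 22 by 22 spots. Of 23232 spots, 960 carried no oligonucleotide and 260 held buffer, and both served as empty spots. Spots with a uniformity or population outlier flag in either channel were left out, between 1.29% and 10.4% of probe spots per array, and saturated spots were kept. Background was corrected with normexp (offset 50) on the mean and background median signals, and ratios were normalized within each array by loess with weight 0 on empty, control and flagged spots, in limma 3.58.1 (R 4.3.3). Signs were turned to log2(embryo/control), spots of a probe were averaged (8 IDs had more than 1 spot), and the dye-swap arrays of a replicate were averaged where both had a value. Probes with at least 2 of the 3 replicate ratios were tested against 0 with lmFit and eBayes, two-sided, and p-values were adjusted by Benjamini-Hochberg. The minimum of 2 replicates was set after the files had been seen.

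The planned filter asked for a spot well above background in at least 4 of the 6 arrays in the channel of 1 condition. The scanner flag it uses was set for 99.2% to 100% of probe spots per channel, and also for empty spots, so this filter removed 0 probes. Filters on the empty spots and on mean intensity were therefore added. The design planned 1 probe per gene name and tests of gene lists; the probe IDs were not paired with genes in the files or in the gene table used here (assembly ARS-UCD2.0), so each probe was tested on its own and the lists were not. For unnamed probes at most 2 IDs per direction are printed: those with the largest ratio among the 10 higher and 10 lower probes of the rule fixed beforehand (smallest unadjusted p, same sign in all 3 replicates).

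The replicate numbers were checked for pairing on channel levels after loess and Aquantile. Deviations from the group means correlated at 0.693, 0.688 and 0.788 between embryo and control RNA of the same number. Same-numbered RNAs share their arrays, so array effects are part of this. The main design keeps the pairing through the ratio on each array.

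The pipeline from loess onward was tested on simulated data for the comparison of embryo with control, with 200 changed probes, real intensities, dye differences and missing cells, and equal effects in all replicates. Over 19964 probes it recovered 84% of 1.5-fold changes, 96% of 2-fold, 100% of 3-fold and 98% of 4-fold changes, with 19 unchanged probes among 208 calls. Over the 3127 probes above the empty spots it recovered 96%, 98%, 100% and 100%, with 5 unchanged probes among 202 calls. The noise for these 3127 was also drawn from the fit over all probes. In the real data the median SE was 0.058 over all probes and 0.068 over the 3127, so this recovery may be too high. The alternative fit with the replicate as a random block over the 6 arrays called more unchanged probes. These were 54 of 252 calls over 20900 probes, and 17 of 216 over 3816 probes above the empty spots. Each size had 50 probes. Noise was independent between probes, and 200 changed probes make the adjusted threshold easier to reach than a few would. The recovery therefore does not show that 0 calls in the real data exclude changes of these sizes. In the real data the probe OLIGO_11480 was at 3.09-fold with a limma adjusted p of 0.427.

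Alternatives covered the background correction, the normalization, the spot flags, the filter on dim probes, the prior, the threshold, the replicate structure, the dye orientation and each replicate left out. Aquantile, no filter on dim probes and the replicate block on channel levels repeat the main fit. A threshold of 0.01 cannot raise a count of 0. The prior, the threshold and the filters leave each probe's ratio as it is. Those added after the data had been seen are the filters on the empty spots and on mean intensity, the treatment of flagged spots and of the authors' emptied cells, loess within print blocks, the print blocks with raised background, and the restriction to probes measured on all 6 arrays.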

Results

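Bovine oviduct epithelial cells, which line the tube where fertilisation and the first cell divisions take place, were grown as a monolayer for 13 days with or without embryos produced in vitro, which shared the culture for the last 8 days. Total RNA of 3 cultures with embryos and of 3 control cultures was compared on 2-colour arrays of spotted bovine oligonucleotides, numbered by biological replicate. Each array held the embryo and the control RNA of 1 replicate number. Every pair was hybridised on 2 arrays, with Cy5 on the embryo RNA in one and on the control RNA in the other, which gave 6 arrays and 3 replicate ratios. The study asked which genes the early embryo regulates in these cells.

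The array carried 21586 probe IDs on 21632 spots, with 1220 empty spots and 380 spots of control type. The gene name cell was filled for 0 spots, and the probe IDs do not occur in the gene table used here, so probes are given without gene names and the gene lists fixed beforehand could not be tested. Signal above background differed between arrays. The share of probe spots brighter than the 95th percentile of the empty spots in both channels ran from 21.9% to 72.2% per array. The lowest share belonged to the replicate 1 array with embryo RNA in Cy5, where the Cy3 background was raised in print blocks 37 to 48 at one end of the slide. With the threshold taken from the empty spots of the other blocks, its share was 46.3%. This share still counts the probe spots of blocks 37 to 48, which can pass in Cy3 through the raised background itself. The number of arrays limits the precision of every value below.

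**Figure D1:**
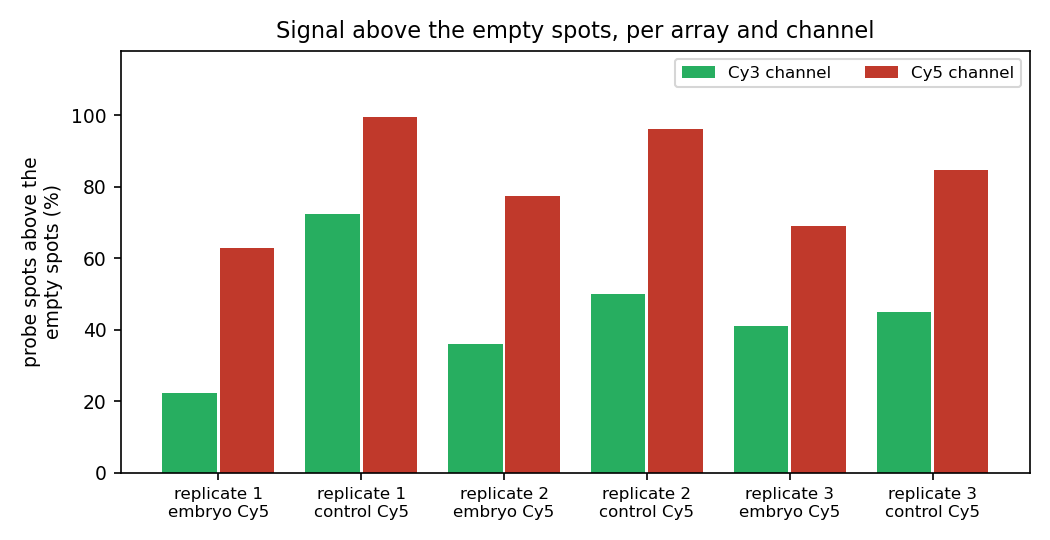
Percentage of probe spots (y axis) above the 95th percentile of the empty spots, per array (x axis), with green bars for the Cy3 channel and red bars for the Cy5 channel. The Cy3 channel ran from 22.2% to 72.2% and the Cy5 channel from 62.9% to 99.4%.

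A small set of probes was brighter with embryos in replicates 2 and 3. Of the 17254 probes measured on all 6 arrays, 12 had a log2(embryo/control) of 1 or more on both arrays of replicate 2, and 8 had one on both arrays of replicate 3. All 8 were among the 12, whereas 0.00556 shared probes would be expected of independent lists of these lengths (one-sided Fisher's exact test across probes, p = 2.55e-27, probes not being independent replicates). That expectation counts all 17254 probes as able to reach the threshold, dim ones included. The 1781 of them above the empty spots in both channels on all arrays held 6 such probes in replicate 2 and 3 in replicate 3. Of those, 3 were shared, against 0.0101 expected. No probe was at log2 -1 or lower on both arrays of any of the 3 replicates, and 0 probes reached 1 on both arrays of replicate 1. The 8 shared probes had a mean log2 ratio of 1.99 in replicate 2 (3.96-fold) and 1.89 in replicate 3 (3.71-fold), and the highest single probe was 8.9-fold brighter in replicate 2 and 8.1-fold in replicate 3. For 5 of the 8 the control channel was not above the empty spots on 1 or 2 of the 6 arrays, so these folds are approximate. Each alternative gave its own set of such probes. The highest probe of the set ran from 2.9-fold to 11.5-fold in replicate 2 and from 2.7-fold to 12.7-fold in replicate 3. It was lowest with the authors' emptied cells left out, a set of 3 without the 8.9-fold probe. It was highest with processed signals and median centring. In replicate 1 the mean of the 8 shared probes was 0.44 (1.35-fold), with 8 of 8 above 0. The count of 8 was 290 with the scanner software's processed signals and median centring in place of loess, 18 with outlier spots kept, and 3, with 2 of the 8 among them, with the authors' emptied cells left out in place of the outlier flags. Of the 290, 285 were measured in replicate 1, where 205 were above 0. With these processed signals 2 probes were at -1 or lower on all 4 arrays of replicates 2 and 3.

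**Figure D2:**
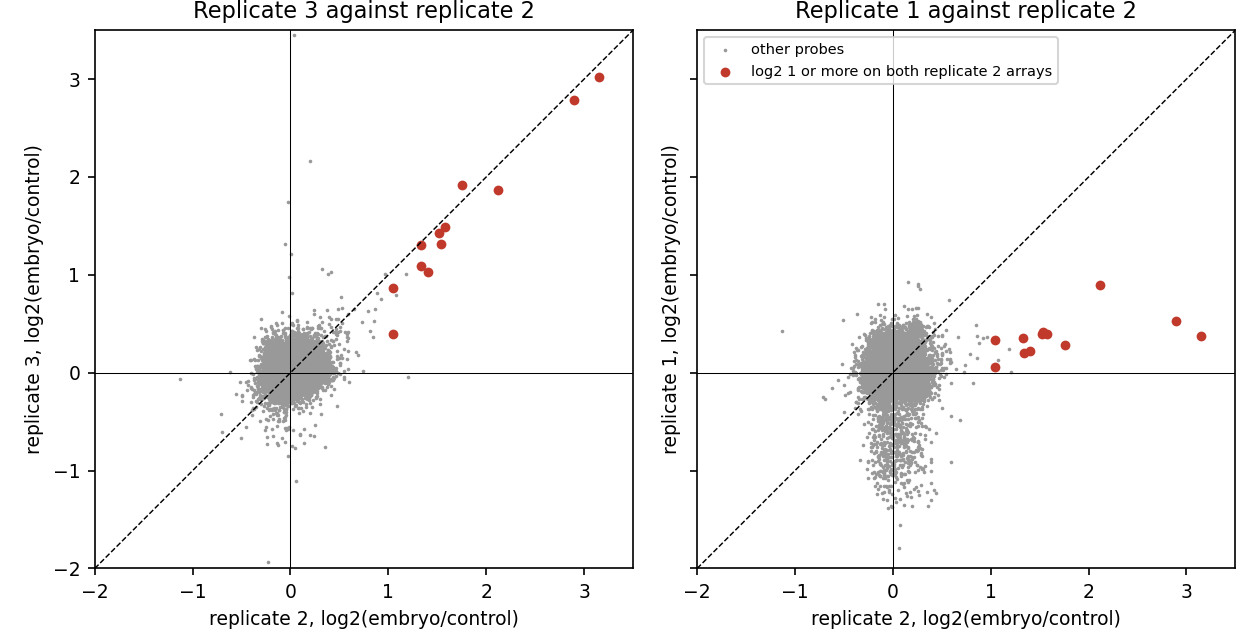
Mean log2(embryo/control) of each probe measured on all 6 arrays, with replicate 2 on the x axes and replicate 3 (left) or replicate 1 (right) on the y axes, the dashed line marking equal values. The 12 red probes, chosen on replicate 2, averaged 1.73 there, 1.54 in replicate 3 and 0.37 in replicate 1, and the grey tail below 0 on the right belongs to replicate 1.

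At a lower threshold of log2 0.5, 27 probes were higher with embryos on both arrays of replicate 2, 21 on both arrays of replicate 3 and 8 on both arrays of replicate 1. Replicates 2 and 3 shared 18 of these. Replicate 1 shared 0 with either, where 0.0125 and 0.00974 would be expected of independent lists. In replicate 1, 26 of the 27 probes chosen on replicate 2 and 20 of the 21 chosen on replicate 3 had a ratio above 0. In the opposite direction, 2 probes in replicate 2, 1 in replicate 1 and 0 in replicate 3 were at -0.5 or lower on both arrays. Both thresholds were chosen after the ratios had been seen.

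**Figure D3:**
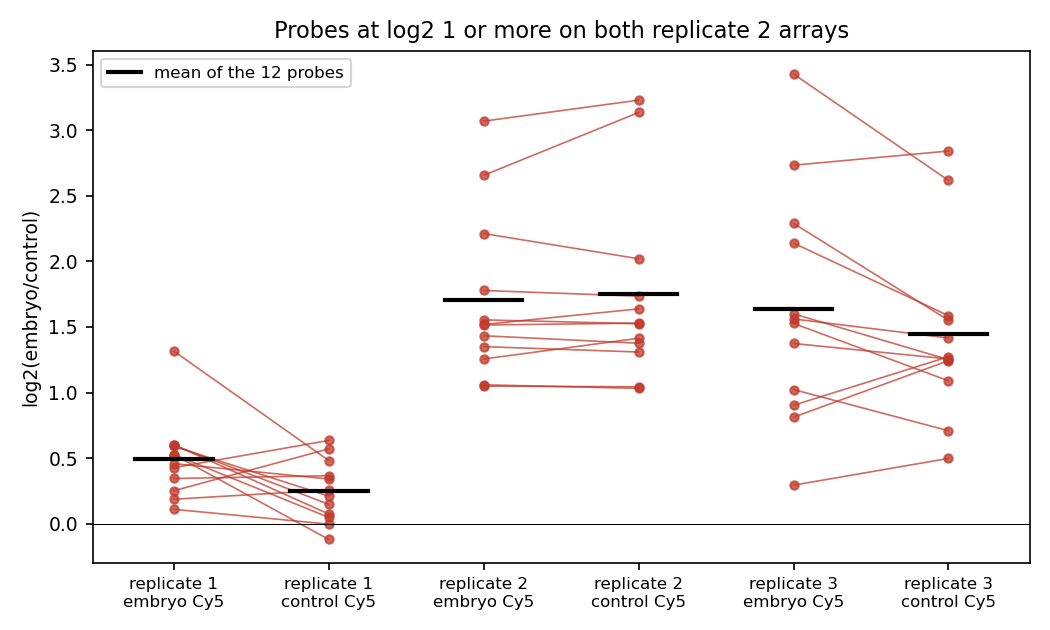
Log2(embryo/control) on each array (y axis) of the 12 probes at 1 or more on both arrays of replicate 2, with thin lines joining the dye-swap arrays of a replicate and black bars at the mean of the 12 probes. The mean was 0.50 and 0.25 on the replicate 1 arrays, 1.70 and 1.75 on those of replicate 2, and 1.64 and 1.44 on those of replicate 3.

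Over the 3 replicates together, no probe passed the planned test. With limma on the 3 replicate ratios, 0 of 19964 probes had a Benjamini-Hochberg adjusted p under 0.05, and the smallest adjusted p was 0.427. At an unadjusted p under 0.05 there were 2077 probes, 1422 higher and 655 lower with embryos, against 998.2 expected by chance from independent tests. The balance was the other way among the 3127 probes above the empty spots described below, with 188 higher and 294 lower at that p, and even among the probes with 1 sign on all 6 arrays, with 399 higher and 395 lower. The fit with the replicate as a random block over the 6 arrays also gave 0. Without replicate 1 there were 70 probes past the threshold, 61 higher and 9 lower, and without replicate 2 or replicate 3 there were 0. Each probe of the fit without replicate 1 rests on 2 ratios.

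Of the probes that came next by the rule fixed before the data were examined, the 10 higher ones by smallest p with the same sign in all 3 replicates lay between log2 0.32 and 1.62, and the 10 lower ones between -0.52 and -0.26; none passed the threshold. The probes so chosen cannot change sign when a replicate is left out. The values after ± are limma's moderated SE, drawn towards the spread of all probes, and the SD is that of the 3 replicate ratios. The largest of the higher ones was OLIGO_11480, at a log2 ratio of 1.625 ± 0.227 (SD 0.643, n = 3, 3.09-fold, limma adjusted p = 0.427). Its replicate ratios were 0.898, 2.116 and 1.863, and it was above 0 on all 6 arrays. OLIGO_10039 had a log2 ratio of 0.44 ± 0.059 (SD 0.11, n = 3, 1.36-fold, limma adjusted p = 0.427) and was above 0 on all 6 arrays. Among the lower probes, OLIGO_07057 had -0.524 ± 0.091 (SD 0.228, n = 3, limma adjusted p = 0.427), with 1 of its arrays at 0.104. OLIGO_07057 lay in the print blocks with raised Cy3 background on the replicate 1 array with embryo RNA in Cy5, where it had -0.348. Without that spot only replicates 2 and 3 remained, at -0.654, and it would not have met the rule. OLIGO_11263 had -0.407 ± 0.077 (SD 0.177, n = 3, limma adjusted p = 0.427), below 0 on all 6 arrays.

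Since the planned filter removed 0 probes, the same fit was also run on the 3127 probes above the 95th percentile of the empty spots in both channels on all 6 arrays, a filter chosen after the files had been seen. There, 20 probes passed an adjusted p of 0.05, 14 higher and 6 lower. The 14 higher probes lay between 1.25-fold and 3.09-fold and the 6 lower ones between 1.26-fold and 1.73-fold; 12 of the 20 had been measured in all 3 replicates. OLIGO_11480 (limma adjusted p = 0.028), OLIGO_10039 (0.0469) and OLIGO_07057 (0.0469) were among them, and OLIGO_11263 (0.0591) was not. This count depends on the processing. It was 0 of 1781 with only probes measured on all 6 arrays, 0 without background subtraction, 3 without the probes of print blocks 37 to 48, and 0 with a filter on mean log2 intensity above 8 in its place. It was 127 without replicate 1, 1 without replicate 2 and 0 without replicate 3. With median centring in place of loess the calls were 91 higher and 4 lower, and with processed signals and median centring together they were 18 higher and 532 lower. These settings shifted the bright probes together, by a median of 0.145 and -0.198 on the log2 scale over the 1781 measured on all 6 arrays, so the balance of calls follows that common shift.

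Replicates 2 and 3 resembled each other more than either resembled replicate 1. Across the 17254 probes measured on all arrays, Pearson's r of the replicate ratios was 0.316 between replicates 2 and 3, 0.126 between replicates 1 and 2, and 0.131 between replicates 1 and 3. Without print blocks 37 to 48 on the affected array these were 0.326, 0.202 and 0.184 over 13074 probes. Per the scan dates in the file headers, each replicate's arrays were scanned on a day of their own. Replicate and scan day therefore coincide, and the arrays of each day held both conditions.

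Differences between the dyes were, at the median, larger than those between the conditions. Between the dye-swap arrays of a replicate, the ratios turned to embryo over control correlated at -0.279 to -0.137 across probes. Among the 1781 probes above the empty spots and measured on all arrays, this was -0.379 in replicate 1, 0.487 in replicate 2 and 0.105 in replicate 3. Over all probes, arrays of the same dye orientation from different replicates correlated at 0.139 to 0.433. The median absolute dye term was 0.094 on the log2 scale, against 0.060 for the embryo term, over the 19964 probes. No probe passed the limma test for the dye term over these probes, with 4331 at an unadjusted p under 0.05. Among the 3127 probes above the empty spots, 6 did.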

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

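Spots of control type were not part of the comparison and were looked at after the main result was known. Of their 29 names, 8 were above the 95th percentile of the empty spots in all 12 channels, so they carried signal that the comparison did not use. The highest of the 8 had a mean log2(embryo/control) of 0.59 ± 0.158 (SD, n = 3; 13 spots; 1.51-fold), above 0 in all 3 replicates, and the next highest had 0.109. The lowest was PPIA, which encodes cyclophilin A and is often used as a reference gene, at -0.11 ± 0.108 (SD, n = 3), below 0 in 2 of 3 replicates. PPIA was the only 1 of the 29 names that the gene table matched. Median centring moved PPIA to 0.064 and the highest name to 0.773, and processed signals with median centring moved them to -0.295 and 0.394. Both moved together, as did the bright probes, so these shifts say nothing about either name alone. No explanation was tested for either.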

How the results depend on the processing

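The alternatives on empty spots, mean intensity, spot flags, emptied cells, print blocks and probes measured on all 6 arrays were chosen after the data had been seen. The count of 0 in the planned test stayed at 0 under 23 of 29 alternatives. These include every planned one that was run except leaving out replicate 1 (0 to 70 over the 3 replicates left out). Aquantile, no filter on dim probes and the 0.01 threshold could not change the count. It was 9 with the authors' emptied cells left out in place of outlier flags (7 of the 9 measured in all 3 replicates). It was 7 with the raised-background blocks left out on the affected array (0 of the 7). The filter on empty spots gave 20 in both channels (12 of the 20) and 3 in 1 condition's channel (0 of the 3). With those blocks left out and the filter set by the empty spots outside them, the count was 29 (12 of the 29). For the pairing, channel levels gave 0 probes with no replicate block (360 at an unadjusted p under 0.05) and 0 with it.

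The count of 20 above the empty spots stayed within 1.5 times in 5 of 23 alternatives. It was 0 without background subtraction, 34 with offset 16, 550 with processed signals and median centring, 95 with median centring alone, 124 with the authors' emptied cells, 63 and 3 with the raised-background blocks left out on 1 array or on all, 31 with loess within print blocks, 47 and 0 at adjusted p of 0.10 and 0.01, 34 with the replicate block as a random effect, 0 with no replicate block, 103 and 3 on arrays with embryo or control RNA in Cy5, and 0 on probes measured on all 6 arrays. Leaving out a replicate gave 0 to 127. The count of 8 raised probes was 290 with processed signals and median centring, 18 with flagged spots kept and 3 with the authors' emptied cells, and within 1.5 times in 6 of 9. The Aquantile step is among the 5 and the 6 and could change neither.

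Many settings cannot change the ratios of the 4 named probes, chosen for 1 sign in all replicates. They kept it wherever they had a value. OLIGO_11480 had none with the authors' emptied cells, and OLIGO_07057 none there or without the probes of the raised-background blocks. OLIGO_11480 ranged from 1.362 to 1.989 (adjusted p 1.39e-07 to 1), OLIGO_10039 from 0.281 to 0.596 (0.0167 to 1), OLIGO_07057 from -0.756 to -0.293 (0.00111 to 1) and OLIGO_11263 from -0.665 to -0.252 (0.00891 to 1). Both OLIGO_10039 and OLIGO_11263 were lowest with processed signals and median centring and highest with median centring alone. Not run were the deposited value table, which holds no ratio, and the summary per gene and gene lists, which need gene names.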

Other observations

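The tests of ratio compression, of choosing probes on replicate 2, of dye bias and of exchanged samples were chosen only after their results had been seen.

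The 12 probes raised on replicate 2 moved less in replicate 1, with a slope through 0 on replicate 2 of 0.208 ± 0.029 (SE), against 0.918 ± 0.036 for replicate 3. Choosing probes on replicate 2 would lower both slopes alike, and they differed by 0.71 ± 0.046. These SEs measure scatter across the 12 probes and treat the slopes as independent, while each slope rests on a single replicate. Ratio compression by background would spare bright probes, and the slope was 0.243 ± 0.044 for the 6 brighter ones and 0.166 ± 0.033 for the dimmer ones. Brightness was the mean over both channels and all arrays. Not all of the brighter probes had a control channel above the empty spots on every array, so this split cannot exclude compression. Against a raised level in the control RNA, the median control level in replicate 1 was -0.105 ± 0.123 relative to replicate 3. The embryo level was at -0.978 ± 0.169. These are bootstrap SEs across the 12 probes, while each level rests on a single culture. Not all of the 12 had a control channel above the empty spots on every array, which weakens this argument. The cause stays open. A weaker response of replicate 1 cells, partial mixing of RNA and embryo RNA in replicates 2 and 3 were not tested against each other. Scan day and replicate also coincide.

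The ratios of the replicate 1 arrays correlated negatively after turning, at -0.279 across probes. Dye differences of replicate 1 correlated with those of the other replicates at 0.321 and 0.395, which is consistent with a dye bias of the probes that all arrays share. The correlation was -0.224 with loess within print blocks, which argues against position by block as the whole cause. An exchange of the RNA samples on 1 array is argued against by the 8 probes raised in replicates 2 and 3, whose medians were 0.275 ± 0.131 and 0.527 ± 0.07 (bootstrap SE) on the replicate 1 arrays. With processed signals and median centring, the 290 probes raised in that setting had medians of -0.262 and 1.804 on the same arrays. Under the other alternatives both medians stayed positive.

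In replicate 1, 463 probes had a mean log2 ratio of -0.5 or lower, against 13 in replicate 2 and 42 in replicate 3. Of these, 72.6% lay in 5 of the 48 print blocks and 97.4% in blocks 37 to 48, which hold 25.1% of the probe spots. Their median was -1.743 on the array with embryo RNA in Cy5 and 0.135 ± 0.01 on its dye swap, which argues against a lower RNA level in the exposed cells. A local raised background on the first array is a candidate explanation, since the 95th percentile of its Cy3 empty spots was 412.6 in those blocks and 143.9 in the others.

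With 3 replicates there are 4 ways of signing the replicate ratios, too few for a share under 0.05. In the planned test all 4 gave 0 probes (highest other count 0), which decides nothing; at an unadjusted p under 0.05 the real signs gave 2077 probes and the others 684, 520 and 461. Among the probes above the empty spots the real signs gave 20, 1 of the 4 ways with as many, and the highest other count was 3.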
